A study of Mus musculus with 20 samples.

How the data were processed

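The series holds 20 samples from tumour-infiltrating cells of mice with TC-1 tumours: 8 gene expression and 8 surface protein libraries, 1 of each per arm (Ctrl, Vax A, Vax B, Vax C) and gate (CD45+CD3- and CD3+), and T cell receptor libraries of the CD3+ gate. Gene and antibody values came from 8 matrices, each holding both kinds for 1 arm and gate, and receptor contigs from 3 files (Ctrl, Vax B, Vax C). No receptor file of Vax A was available, so that library was not analysed here. The control is called Ctrl A in the titles of the surface protein and receptor libraries and Ctrl C in those of the gene expression libraries. Both names lead to the same matrices, and 98.9% of the receptor barcodes of the control were among its kept CD3+ cells, so 1 control is taken here. The protocol text also mentions cGAMP, a ligand of STING, but no sample label carries it. Harvest days (17, 22 and 27) are listed for the series as a whole, and the letters A, B and C were not assigned to days.

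The deposited matrices hold raw UMI counts per feature and cell, made by the authors with Cell Ranger 4.0.0 against mm10 (GRCm38) per the file headers and processing notes. Each matrix has 32285 genes, of which 32235 were found in GENCODE M21 and given positions on GRCm38, and 19 antibody features, 18 antibodies and the E7 dextramer. The deposited receptor files give read and UMI counts per assembled contig, with the CDR3 sequence, the V gene and a clonotype identifier, in the layout of Cell Ranger's receptor output. Seurat is named in the notes, but its role and version are not given in the sources used here, nor is the filter behind the deposited barcodes. Alignment and cell calling were thus the authors', and multi-mapped reads of near-identical genes are already resolved or lost in these counts.

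The CD45+CD3- matrices of Ctrl, Vax A, Vax B and Vax C held 12242, 10610, 9744 and 9157 barcodes with 127941687, 109390020, 110408093 and 119830043 gene UMIs, at medians of 9903.5, 9811.5, 10509 and 11878 per barcode. The CD3+ matrices held 11784, 12919, 10431 and 9732 barcodes with 98059669, 104391379, 77366093 and 73784406 gene UMIs, at medians of 5912, 6588, 6538 and 5975.5. Antibody UMIs were 47725852, 53846504, 43783872 and 52939606 in the CD45+CD3- matrices and 38989085, 44445142, 38464810 and 45929817 in the CD3+ matrices. Receptor files held 29112, 28224 and 27024 contigs for Ctrl, Vax B and Vax C.

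Barcodes with at least 300 genes and at most 10% mitochondrial UMIs were kept: 11701, 10142, 9457 and 8965 in the CD45+CD3- gate and 11433, 12554, 10070 and 9534 in the CD3+ gate. Scrublet, run as in scanpy 1.11.5 on each library, marked at most 0.0335% of a library, under the 0.5% below which no doublets were to be removed, so none were. The 4 libraries of a gate were clustered together and the gates apart, without batch integration: 2000 variable genes (without receptor, immunoglobulin, mitochondrial and ribosomal protein genes), 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, seed 1). Clusters were named from fixed marker genes and carry the suffix "-like". Clusters with T, NK or B cell genes in at least 50% of cells were called mixed if Adgre1 was in at least 30% or if a myeloid or non-immune marker set scored highest. Mixed clusters belong to no T cell or myeloid class, and clusters without a clear name were left unnamed. A cluster whose monocyte and macrophage scores lay within 0.3 of each other was called intermediate. That limit was set after the data were examined, and the intermediate clusters were added to the monocyte-like and macrophage-like cells to form the mononuclear phagocyte-like class, which had been planned as those 2 names together. Marker genes that define a class are not reported as results of its share.

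For each class and arm the UMIs of all cells were summed and divided by the sum over all genes to give CPM. Mononuclear phagocyte-like sums were 114571085, 85363616, 91689948 and 103923576 UMIs from 10125, 7422, 7036 and 7433 cells, and CD8 T-like sums 20408955, 42406418, 64476282 and 43628930 UMIs from 2036, 3774, 7809 and 6381 cells, in the order Ctrl, Vax A, Vax B, Vax C. Vax A, Vax B and Vax C were each compared with Ctrl, and Vax B and Vax C with Vax A, as log2 ratios of CPM. The 95% interval of a ratio is the exact conditional binomial interval of the 2 sums, and that of a share the exact (Clopper-Pearson) binomial interval (scipy 1.17.1). Such intervals cover counting error only, not differences between mice, sorts or runs, and a share of 0 is given with the limit set by 3 counts. For named genes with at least 100 UMIs in 1 library, the median half-width of the interval was 0.048 in mononuclear phagocyte-like and 0.079 in CD8 T-like cells. The widest of these were 0.47 for Ifnb1 and 1.63 for Cxcl9, and named genes with fewer UMIs reached 2.17 for Tox and 6.29 for Arg1, in the same classes. With 1 library per group, no test across samples, p-value or standard error could be had, and a larger number of cells does not replace replicate mice.

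Gene lists, 21 in all, were fixed before the data were examined: interferon-stimulated genes, cytosolic nucleic acid and TLR sensing, interferon-gamma response, MHC class I presentation, MHC class II presentation, co-stimulation of T cells, inflammatory cytokines and NF-kB targets, immunosuppressive myeloid genes, lipid-handling and lysosomal macrophage genes, complement, monocyte and neutrophil chemokines, hypoxia and glycolysis, oxidative phosphorylation, cell cycle, dissociation and heat-shock stress, T cell exhaustion, T cell cytotoxicity and effector cytokines, naive, memory and stem-like T cell genes, T cell activation and co-stimulation receptors, regulatory T cell effector genes, and ribosomal proteins. A member counted as measured with a CPM of at least 20 in 1 of the 2 libraries. Each list is described by its median log2 ratio, the 95% bootstrap interval over its members, and the number of members at least 1.5-fold higher or lower. The median was also placed among 10000 random lists of the same size matched on mean CPM. In mononuclear phagocyte-like cells the interferon-gamma response stood at percentile 100 in each vaccinated arm and the cell cycle list at percentile 0, and in CD8 T-like cells of Vax B and Vax C the exhaustion list stood at percentile 100. List members share regulation, so such a percentile is a description and not a test. Some genes are in more than 1 list. Other classes needed at least 200 cells in both libraries, which left out neutrophil-like cells and the conventional DC-like and NK-like cells of Vax C.

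Genes named in the text were chosen by a rule fixed at the same time as the lists. It takes the 10 largest and 10 smallest ratios to Ctrl in mononuclear phagocyte-like and CD8 T-like cells, of which fewer may be named from the extreme inwards, among genes with a CPM of at least 50 in 1 library, at least 100 UMIs, at least a 2-fold difference and detection in at least 5% of cells of the higher library, without immunoglobulin, receptor, haemoglobin, mitochondrial, ribosomal, Gm and Rik genes and markers of other classes. It also takes the 4 members of each list with the largest absolute ratio, and always Cgas, Sting1 (Tmem173 in the files), Tbk1, Irf3, Irf7, Ifnb1, Pdcd1, Cd274, Ifng, Gzmb, Tcf7, Tox, Foxp3, Arg1, Nos2, Cxcl9, Cxcl10 and H2-Ab1. Some genes that this rule selects are not reported here.

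Antibody counts are given as the median UMIs per cell of a class and as the share of the class's antibody UMIs. Cells with at least 10 dextramer UMIs were counted as dextramer-binding, a minimum chosen after the counts were seen, and cells without a dextramer UMI were also compared on their own. A clone was a set of barcodes with identical productive TRA and TRB CDR3 nucleotide sequences, expanded from 10 cells on, and 100 random draws gave values at equal numbers of cells. Alternatives tried were a stricter cell filter (500 genes, 5% mitochondrial UMIs), Leiden resolutions of 0.5 and 2.0, TMM scaling (edgeR 4.0.16 in R 4.3.3), the mean of each cell's CPM, cells thinned to 2000 UMIs, no filter on low values with 1 added to the CPM, removal of the highest Scrublet scores at 0.8% per 1000 barcodes, and other counts of antibodies, dextramer and clones. The ratios and intervals were tested on simulated data, where the intervals held the simulated ratio for 94% to 100% of genes. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.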

Results

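TC-1 is an established mouse lung epithelial line that expresses the E7 oncoprotein of human papillomavirus and grows as a tumour in C57BL/6 mice. Mice were given PBS (Ctrl) or a vaccine of 0.5 µg E7 peptide with 30 µg PC7a, a pH-sensitive polymer used as an antigen carrier that also activates the innate sensor STING. Tumour-infiltrating leukocytes were sorted into a CD45+CD3- gate and a CD3+ gate, and each sort was run as a droplet single-cell library. Every droplet gave transcript counts, counts of 18 barcoded antibodies, and counts of an E7 dextramer, a barcoded multimer of E7-loaded MHC class I that binds T cell receptors specific for E7. Receptor sequences of the CD3+ cells were available for Ctrl, Vax B and Vax C. The labels list harvests on days 17, 22 and 27 and name the vaccinated samples Vax A, Vax B and Vax C without tying a letter to a day, so the letters are used here and no order in time is assumed. Each arm and gate was 1 library, so no value has a replicate, no test between arms could be made, and all bracketed intervals are 95% intervals of counting error alone. All 3 vaccinated libraries of a gate are compared with the same Ctrl library, whose harvest day is not given either, so day and vaccination are not separated in any ratio to Ctrl.

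Macrophage-like cells made up 59.5% (58.6% to 60.4%) of the kept CD45+CD3- cells in Ctrl, 11.3% (10.6% to 11.9%) in Vax A, 6.87% (6.37% to 7.40%) in Vax B and 30.8% (29.9% to 31.8%) in Vax C. Monocyte-like cells made up 9.43% (8.90% to 9.97%) in Ctrl against 46.6% (45.6% to 47.6%) in Vax A, 61.1% (60.1% to 62.1%) in Vax B and 41.8% (40.7% to 42.8%) in Vax C. NK-like cells, which kill without an antigen receptor, were 2.27% (2.01% to 2.56%) of the gate in Ctrl, 11.9% (11.2% to 12.5%) in Vax A, 12.0% (11.3% to 12.6%) in Vax B and 1.44% (1.2% to 1.71%) in Vax C. On the log2 scale the macrophage-like share differed from Ctrl by -2.40 in Vax A, -3.12 in Vax B and -0.95 in Vax C, the monocyte-like share by 2.31, 2.70 and 2.15, and the NK-like share by 2.38, 2.40 and -0.66. Clusters between the monocyte and macrophage markers, called intermediate, held 17.6%, 15.3%, 6.42% and 10.3% of the gate in Ctrl, Vax A, Vax B and Vax C. The 3 groups together, called mononuclear phagocyte-like cells, were 86.5%, 73.2%, 74.4% and 82.9%. Conventional DC-like cells, which carry antigen to T cells, were 4.71%, 5.96%, 2.65% and 1.61%, and mature DC-like cells 0.291%, 1.01%, 0.751% and 0.658%. Neutrophil-like cells were 0.949% in Ctrl and 4.04% in Vax C. The split of monocyte-like from macrophage-like cells rests on the marker genes that name the clusters, and at a Leiden resolution of 2.0 the monocyte-like log2 ratios were 1.42 in Vax A, 1.72 in Vax B and 0.86 in Vax C, while the macrophage-like ratios stayed below 0 in all 3.

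In the CD3+ gate, CD8 T-like cells were 17.8% (17.1% to 18.5%) of kept cells in Ctrl, 30.1% (29.3% to 30.9%) in Vax A, 77.5% (76.7% to 78.4%) in Vax B and 66.9% (66.0% to 67.9%) in Vax C. Regulatory T-like cells, marked by Foxp3, were 33.0% (32.2% to 33.9%) in Ctrl, 35.9% (35.0% to 36.7%) in Vax A, 6.15% (5.69% to 6.63%) in Vax B and 4.46% (4.05% to 4.89%) in Vax C. CD4 conventional T-like cells were 10.3%, 8.87%, 3.14% and 2.80% in the same order, and gamma-delta T-like cells 2.97%, 3.79%, 0.377% and 0.147%. The log2 ratio of the CD8 T-like share to Ctrl was 0.76, 2.12 and 1.91 in Vax A, Vax B and Vax C, and that of the regulatory T-like share was 0.12, -2.43 and -2.89. Barcodes with both T cell and myeloid genes were 18.8% of the gate in Ctrl, 0.414% in Vax A, 2.75% in Vax B and 12.7% in Vax C. Taken as a share of T-like cells only, the regulatory T-like ratio of Vax A turned to -0.24.

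**Figure D1:**
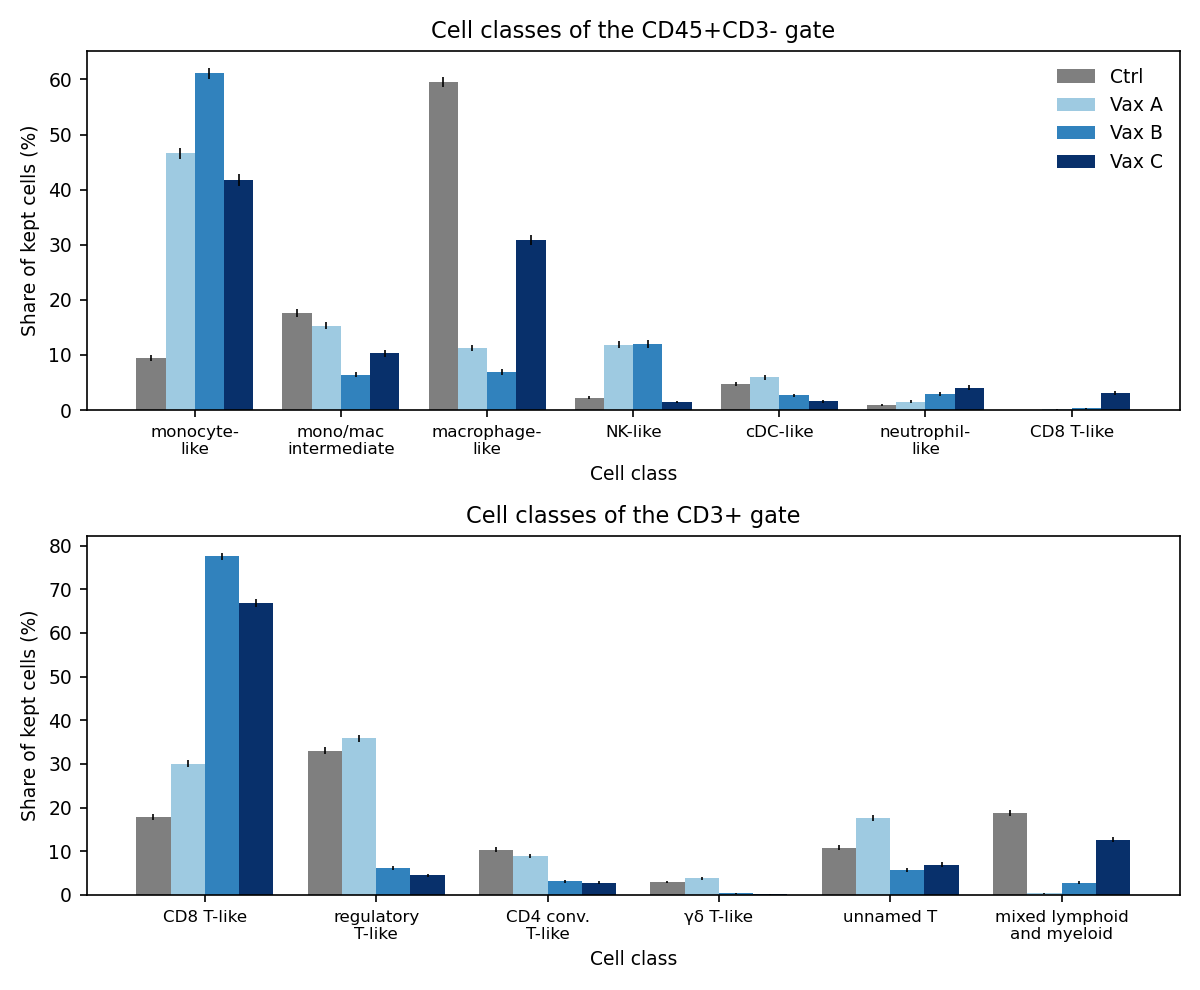
Share of kept cells (%, linear axis) of each cell class in the CD45+CD3- gate (top) and the CD3+ gate (bottom) for Ctrl, Vax A, Vax B and Vax C, 1 library each, with exact 95% binomial intervals as black lines. Macrophage-like cells stand at 59.5% in Ctrl and at 11.3%, 6.87% and 30.8% in Vax A, Vax B and Vax C, and CD8 T-like cells at 17.8% in Ctrl and 77.5% in Vax B.

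In mononuclear phagocyte-like cells of Vax A, genes induced by interferon-gamma stood far above Ctrl. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), a chemokine that draws T cells, had a CPM (UMIs scaled to equal library totals) of 443 against 27.3, a log2 ratio of 4.02 (95% interval 3.97 to 4.07). The guanylate-binding protein gene Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008) was 11-fold higher, and the transcription factor gene Irf1 (ENSMUSG00000018899, chromosome 11, 53770014 to 53778374) 8.91-fold higher. Among the genes that were lower, the log2 ratio was -4.14 (95% interval -4.22 to -4.06) for Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738) and -3.41 (95% interval -3.52 to -3.30) for the mannose receptor Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), which is also 1 of the macrophage markers. Macrophage-like cells, a part of this class, were 59.5% of the gate in Ctrl and 11.3% in Vax A. Of the 19 measured interferon-gamma response genes, 19 were at least 1.5-fold higher, with a median log2 ratio of 2.24 (member bootstrap 1.72 to 2.74). Among genes within the abundance and class limits for naming, the largest ratios were Cnn3 (5.17), Upp1 (4.25), Tgtp1 (4.06), Cxcl9 (4.02) and Acod1 (3.86), among them the GTPase gene Tgtp1 and Acod1, whose enzyme makes itaconate. Within the same limits, the smallest ratios belonged to Pf4 (-4.17), Fcrls (-4.14), Tk1 (-3.74), Mrc1 (-3.41) and Top2a (-3.36).

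Interferon-stimulated genes, which answer type I interferon, were higher over the whole class in Vax A but lower in its monocyte-like cells. Over the class, 15 of 29 were at least 1.5-fold higher and 0 lower, with a median of 0.63 (member bootstrap 0.46 to 0.74) and Ifi47 (1.79), Zbp1 (1.38) and Herc6 (1.12) among those higher. In monocyte-like cells, 9.43% of the gate in Ctrl and 46.6% in Vax A, 15 of 29 were at least 1.5-fold lower (median -0.63). Macrophage-like cells had a median of 0.28, so the value of the class cannot be read as a higher level within its cells. Among genes of cytosolic nucleic acid and TLR sensing, 7 of 17 were at least 1.5-fold higher (median 0.32), including Samhd1 (2.12), Zbp1 (1.38) and Myd88 (1.08) and Tmem173 (ENSMUSG00000024349, chromosome 18, 35733679 to 35740554), the gene of STING, at 0.85 (95% interval 0.81 to 0.89). Cgas, which makes the ligand of STING, had a ratio of 0.05 (95% interval -0.05 to 0.15), Tbk1 0.16, Irf3 0.01 and Irf7 0.40. Ifnb1, the gene of interferon beta, was near the limit of detection, with 1.56 CPM against 0.611 in Ctrl. MHC class I presentation genes had a median of 0.87, with 8 of 13 at least 1.5-fold higher, such as Tap2 (1.50), Nlrc5 (1.40) and Tap1 (1.31). MHC class II presentation genes were level as a group: 1 of 9 was at least 1.5-fold higher, the transactivator Ciita (1.03), and H2-Ab1 stood at 0.01 (95% interval 0.00 to 0.01). That value is -0.24 without the intermediate clusters and -0.01 at a Leiden resolution of 0.5. Of the co-stimulation genes 3 of 7 were at least 1.5-fold higher (median 0.52, but -0.27 in monocyte-like and 0.13 in macrophage-like cells), led by Cd40 (1.58) and Il18 (0.88). Nos2, which makes nitric oxide, rested on few counts, at 13.8 CPM against 1.13 and a ratio of 3.6 (95% interval 3.34 to 3.87), while Cd274, the gene of PD-L1, was at 127 against 25.7 CPM.

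Genes of lipid handling and lysosomes were lower in the mononuclear phagocyte-like cells of Vax A, 9 of 15 by at least 1.5-fold (median -0.75 (member bootstrap -1.48 to -0.35)), with Spp1 (-2.69), Lpl (-2.20), Apoe (-2.12) and Abca1 (-1.52). Cell cycle genes had the lowest median, -2.30 (member bootstrap -2.68 to -1.86), and 16 of 17 were at least 1.5-fold lower, including Cdk1 (-4.20), Rrm2 (-3.86) and Top2a (-3.36), although the 5 measured in monocyte-like cells had a median of 0.57. Complement genes were split: C3 (1.84) was higher and C1qa (-1.59) and C3ar1 (-1.55) lower, with 3 higher and 5 lower of 9 (median -0.65). Monocyte and neutrophil chemokine genes were lower in 7 of 15 and higher in 2, with Ccl7 (-2.21), Cxcl1 (-2.02), Cx3cr1 (-2.00) and Ccl6 (1.99). Inflammatory cytokine and NF-kB target genes went both ways, 5 higher and 4 lower of 14, as did immunosuppressive myeloid genes, 2 higher and 3 lower of 12, with Cd274 (2.30) and Chil3 (1.47) higher. Hypoxia and glycolysis genes had a median of 0.19 (4 of 17 higher, Pfkp at 1.68), dissociation and heat-shock genes 0.48 (7 of 17 higher, Hspa1a at 1.1) and ribosomal protein genes -0.48 (5 of 20 lower). Oxidative phosphorylation genes were level, at a median of 0.02 that became -0.03 when each cell was thinned to the same depth. Arg1 was lower at -2.63 (95% interval -2.91 to -2.35), from 8.76 CPM in Ctrl. Of the genes named here and below, Apoe, C1qa, C1qc, Trem2, Pf4 and Mrc1 are macrophage markers and Chil3 is a monocyte marker. Their ratios over the class are therefore not separate from the shares of its parts.

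Mononuclear phagocyte-like cells of Vax B had higher genes of the interferon-gamma response and of inflammation than those of Ctrl. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute-phase serum amyloid gene, was at 877 CPM against 12.8 in Ctrl, a log2 ratio of 6.10 (95% interval 6.03 to 6.18) that was 3.64 in Vax A, and was followed within the limits for naming by Cnn3 (5.0), Lrg1 (4.75), Upp1 (4.50), Acod1 (4.45), Wfdc21 (4.15), Cxcl9 (4.12) and Lcn2 (3.91). All 20 measured interferon-gamma response genes were at least 1.5-fold higher (median 1.94 (member bootstrap 1.28 to 2.66)), with Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) at 5.04 (95% interval 4.78 to 5.30) and 37.2 CPM. Inflammatory cytokine and NF-kB target genes were higher in 11 of 16 and lower in 4 (median 1.17 (member bootstrap 0.03 to 1.43)), with the interleukin gene Il1a (2.70), the neutrophil chemokine gene Cxcl3 (2.5) and Sod2 (1.62) and Icam1 (1.46). The lowest ratios within these limits were Fcrls (-6.33), Pf4 (-5.25), Hist1h2ap (-4.39), Mrc1 (-4.15) and Tmem119 (-4.03).

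Interferon-stimulated genes of Vax B mononuclear phagocyte-like cells were split, 6 of 29 higher and 5 lower by at least 1.5-fold with a median of 0.21 (member bootstrap 0.00 to 0.39) that was -0.97 in monocyte-like and 0.20 in macrophage-like cells: Ifi47 (1.49) was higher while Ifit3b (-1.37) and Bst2 (-1.15) were lower. With trimmed-mean (TMM) scaling that median was 0.40, and the median of all genes moved from -0.07 to 0.14 in Vax B and from -0.07 to 0.07 in Vax C, so smaller ratios of these pairs are read against that shift. Sensing genes had a median of 0.40 (-0.11 in monocyte-like and 0.43 in macrophage-like cells), 6 of 17 higher, with Samhd1 (2.19), Nlrp3 (1.22) and Zbp1 (1.03), Tmem173 at 0.77 and Cgas at -0.63 (95% interval -0.75 to -0.52). Tbk1 stood at 0.40, Irf3 at -0.25 and Ifnb1, with few UMIs, at 0.03 (95% interval -0.51 to 0.55), and Irf7 at -0.18, or 0.01 with TMM scaling. MHC class I genes were higher in 7 of 13 (median 0.69), whereas class II genes had a median of -0.28, with H2-Aa (-0.45), H2-Eb1 (-0.44) and H2-Ab1 (-0.43). Both parts went the other way for class II, with medians of 0.41 in monocyte-like and 0.70 in macrophage-like cells and 0.47, 0.46 and 0.44 for these genes in monocyte-like cells. Hypoxia and glycolysis genes were higher in 9 of 18 (median 0.65), including Egln3 (2.11), Pfkp (1.71) and Hilpda (1.66). Complement was again split, C3 (2.27) against C1qa (-2.43) and C1qc (-2.28), at a median of -0.53 that was 0.03 with no filter on low values. Chemokine genes were higher in 6 and lower in 8 of 16, with Ccl7 (-3.39) and Ccl12 (-3.03) lowest. Lipid-handling genes were lower in 6 of 15 (median -0.46) and cell cycle genes in 16 of 17 (median -2.78). Immunosuppressive myeloid genes were higher in 5 and lower in 3 of 12, among them Mrc1 (-4.15), Cd274 (2.58) and Chil3 (2.22). Arg1 was at 0.01 (95% interval -0.13 to 0.14) over the class but at -1.38 in monocyte-like cells.

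Mononuclear phagocyte-like cells of Vax C combined the highest Cxcl9 level of the 4 arms with higher MHC class II genes. Cxcl9 was at 921 CPM, a log2 ratio to Ctrl of 5.08 (95% interval 5.03 to 5.13), second within the limits for naming to Saa3 (5.55) and ahead of H2-M2 (3.96), Lrg1 (3.54), Slamf8 (3.46), Upp1 (3.17) and Ccl8 (3.10). MHC class II presentation genes were higher in 7 of 9 (median 0.92 (member bootstrap 0.51 to 1.04)), with Ciita (1.36), H2-Eb1 (1.09), Cd74 (1.04) and H2-Aa (0.99) and H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) at 0.92 (95% interval 0.91 to 0.92). Interferon-gamma response genes were higher in 15 of 18 (median 1.49 (member bootstrap 1.09 to 1.84)), while interferon-stimulated genes were not, with 2 higher, 5 lower and a median of -0.17 (member bootstrap -0.36 to -0.04). Of the latter, Ifi47 (0.96) was higher and Ifit3b (-1.04) and Ifit3 (-0.77) were lower. Fcrls (-2.73), Pf4 (-1.83) and Mrc1 (-1.16), among the lowest in Vax A and Vax B, were nearer to Ctrl. Pf4 and Mrc1 are macrophage markers, and the macrophage-like share was also nearer to Ctrl, at 30.8% of the gate against 11.3% in Vax A and 6.87% in Vax B.

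Lipid-handling and lysosomal genes of Vax C mononuclear phagocyte-like cells had a median of 0.07, with 3 of 15 lower, Spp1 (-1.34), Trem2 (-0.93) and Lpl (-0.74). Cell cycle genes were lower in 15 of 17 (median -1.19), inflammatory genes higher in 7 of 15 (median 0.40, Cxcl3 (1.38) and Icam1 (1.00)) and MHC class I genes higher in 7 of 13 (median 0.60). Complement genes gave -0.15 (0.53 in monocyte-like and 0.27 in macrophage-like cells) with C3 (1.93) higher, and chemokine genes -0.07, or 0.06 with TMM scaling, with Ccl8 (3.10) and Ccl2 (-1.57) at the ends. Sensing genes were higher in 2 of 16, Samhd1 (1.14) and Tmem173 (0.86), with Cgas at -0.52 and Tbk1 at -0.05. Cxcl10 was at -0.04 (95% interval -0.06 to -0.03) over the class, 0.09 with TMM scaling and 0.03 without the intermediate clusters, but at -1.74 in monocyte-like cells (999 against 3326 CPM). Irf3 at -0.08 turned to 0.05 with TMM scaling. Nos2 was higher at 3.48, Cd274 at 1.84 and Arg1 at 0.86 (95% interval 0.75 to 0.98), from 8.76 to 16.0 CPM, and Ifnb1, with few UMIs, at 0.50 (95% interval 0.04 to 0.98). Transcripts of Pdcd1, Ifng, Gzmb, Tcf7, Tox and Foxp3 reached at most 4.78 CPM in these cells of any arm and are not read as expression.

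**Figure D2:**
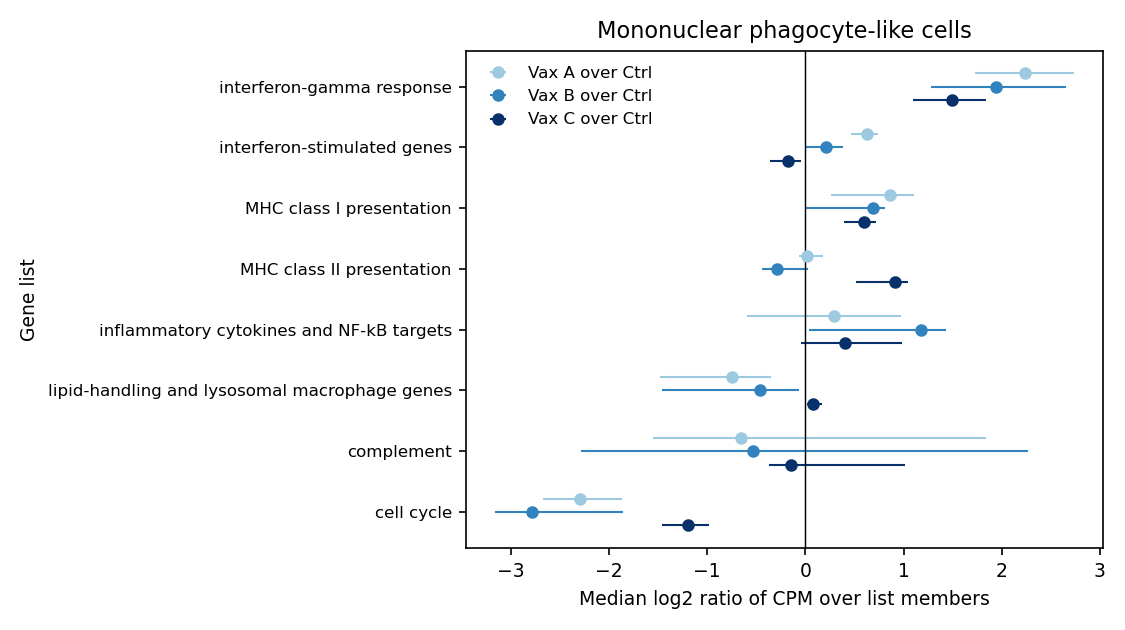
Median log2 ratio of CPM to Ctrl (horizontal axis) over the measured members of each gene list in mononuclear phagocyte-like cells, for Vax A, Vax B and Vax C, with lines for the 95% bootstrap over list members. The interferon-gamma response lies at 2.24, 1.94 and 1.49, and interferon-stimulated genes at 0.63, 0.21 and -0.17.

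Set against Vax A, mononuclear phagocyte-like cells of Vax B had lower interferon-stimulated genes, with 7 of 29 at least 1.5-fold lower and a median log2 ratio of -0.42 (member bootstrap -0.54 to -0.33), as in Ifit3 (-0.91), Ifi44 (-0.89) and Usp18 (-0.84). Inflammatory genes were higher in 7 of 16, including Cxcl3 (3.58), Il1a (1.71) and Cxcl2 (1.38), as were the hypoxia genes Hilpda (1.84), Vegfa (1.62) and Egln3 (1.48). Nos2 stood at 1.44 and Arg1 at 2.63 (95% interval 2.36 to 2.92), while Cxcl9 was nearly level at 0.10. In Vax C over Vax A, interferon-stimulated genes were lower in 20 of 29 (median -0.84 (member bootstrap -0.91 to -0.60)), with Oas2 (-1.32), Oas3 (-1.19) and Cxcl10 (-1.16). Interferon-gamma response genes were lower in 13 of 19 (median -0.88), such as Irgm1 (-1.97) and Tgtp1 (-1.66), even though Cxcl9 was higher at 1.06. The other genes that were higher in Vax C than in Vax A included Ccl8 (4.47), Apoe (2.20) and Mrc1 (2.25), the complement gene C1qa (1.42), Cd74 (1.11) and H2-Eb1 (1.09) and Arg1 at 3.49. Lipid-handling genes were higher in 7 of 14 (median 0.64 (member bootstrap 0.48 to 0.96)).

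Compared part by part, monocyte-like cells of the vaccinated arms had lower interferon-stimulated genes, whereas interferon-gamma response genes were higher in monocyte-like and macrophage-like cells alike. Within monocyte-like cells, 15, 26 and 24 of 29 such genes were at least 1.5-fold lower than in Ctrl monocyte-like cells in Vax A, Vax B and Vax C (medians -0.63, -0.97 and -0.96), with Ifit3b at -2.39, -3.10 and -2.44. Within macrophage-like cells the medians were 0.28, 0.20 and -0.47. The medians of the interferon-gamma response genes were 0.90, 0.73 and 0.44 in monocyte-like cells and 1.66, 2.11 and 1.50 in macrophage-like cells. Cxcl9 in macrophage-like cells was at 3.23, 5.05 and 6.24, and in monocyte-like cells at 2.11, 1.98 and 2.49. MHC class II genes were higher in macrophage-like cells of every vaccinated arm (medians 0.67, 0.70 and 1.27), and likewise in monocyte-like cells (0.53, 0.41 and 1.38), although the whole class showed this in Vax C alone. Cell cycle genes were also lower within macrophage-like cells, at medians of -1.62, -1.22 and -0.82. The parts differ in their clusters between the arms as well. Thus 1 cluster held 595 of 1103 monocyte-like cells in Ctrl and 592 of 3743 in Vax C, and another held 44 of 6967 macrophage-like cells in Ctrl and 1423 of 2764 in Vax C. Values of the class and of its parts mix levels within clusters with shares of clusters.

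CD8 T-like cells of Vax A carried more Ifng and Ccl4 transcripts than those of Ctrl, most of all in the cells that bound the dextramer. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), the gene of interferon-gamma, was at 1337 CPM against 148, a log2 ratio of 3.18 (95% interval 3.12 to 3.23), and the chemokine gene Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683) had a ratio of 3.03 (95% interval 3.0 to 3.07). In the 582 cells with the dextramer, Ifng was at 4175.5 and Ccl4 at 8200 CPM, against 225 and 491 in the 2526 without a dextramer UMI. Cytotoxicity genes of the latter had a median of 0.0211 over Ctrl (member bootstrap -0.46 to 0.31), with 5 of 22 at least 1.5-fold higher and 7 lower. Within the limits for naming, next came Zbtb32 (1.56), Sv2c (1.54) and Gadd45b (1.38) and the inhibitory receptor gene Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705) at 1.37 (95% interval 1.32 to 1.42). Several granzyme genes were lower, with Gzmg (-4.95), Gzmd (-3.04), Gzme (-2.77) and Gzmc (-2.65), while Gzmb, the main granzyme, was at 0.48 (95% interval 0.47 to 0.50). Cytotoxicity genes as a list were split, 6 higher and 6 lower of 22 (median 0.20). Exhaustion genes were higher in 6 of 14 (median 0.46 (member bootstrap 0.27 to 0.78)), with Rgs16 (1.1), Tigit (0.86) and Tnfrsf9 (0.80) and Pdcd1, the gene of PD-1, at 0.43. Naive, memory and stem-like genes were level (median 0.06 (member bootstrap -0.08 to 0.29), 0 of 16 at least 1.5-fold away), with Tcf7 at 0.09, which was -0.02 as the mean of each cell's CPM and -0.03 after thinning. Cell cycle genes were lower in 15 of 21 (median -0.87), such as Ube2c (-1.89) and Nusap1 (-1.61).

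CD8 T-like cells of Vax B and Vax C had more inhibitory receptor transcripts than those of Ctrl. Havcr2 (ENSMUSG00000020399, chromosome 11, 46454935 to 46481255), the gene of TIM-3, was 5.16-fold higher in Vax B and 5.88-fold higher in Vax C, Tigit (ENSMUSG00000071552, chromosome 16, 43648867 to 43664146) 5.82-fold and 6.64-fold. The log2 ratio of Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553) was 1.98 (95% interval 1.94 to 2.03) in Vax B and 2.01 (95% interval 1.96 to 2.05) in Vax C. Stem-like genes were lower: Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014) was at 26.2 CPM in Vax B against 165 in Ctrl, a ratio of -2.66 (95% interval -2.74 to -2.57), and its ratio was -1.75 (95% interval -1.83 to -1.67) in Vax C. Exhaustion genes were at least 1.5-fold higher in 13 of 17 measured members in Vax B (median 1.70 (member bootstrap 0.88 to 2.23)) and in 15 of 17 in Vax C (median 1.75 (member bootstrap 1.45 to 2.01)). Their largest ratios in Vax B were Lag3 (2.59), Rgs16 (2.58), Tigit (2.54) and Havcr2 (2.37) and in Vax C Rgs16 (3.04), Lag3 (2.76), Tigit (2.73) and Havcr2 (2.56). Tox, a transcription factor of lasting T cell dysfunction, was at 0.88 and 1.80 (95% interval 1.67 to 1.94).

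Naive, memory and stem-like genes of CD8 T-like cells were lower in 11 of 16 in Vax B (median -1.19 (member bootstrap -1.93 to -0.46)) and in 9 of 16 in Vax C (median -0.85 (member bootstrap -1.58 to -0.42)). Besides Tcf7 these included Id3 (-2.79) and Xcl1 (-2.07) in Vax B and Id3 (-1.74) and S1pr1 (-1.70) in Vax C. Cytotoxicity and cytokine genes were higher in 13 and 14 of 22 and lower in 4 and 4: Ifng was at 1.96 in Vax B and 2.80 in Vax C, Ccl4 at 2.56 and 2.92, and Gzmc at -2.43 and -3.27. Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260) was at -0.22 in Vax B, or 0.16 as the mean of each cell's CPM and 0.14 after thinning, and at -0.50 in Vax C. Within the limits for naming, which leave out markers of other classes such as Areg, the largest ratios were Serpinb1a (3.64), Sdcbp2 (3.57), Csf1 (3.46) and Serpinb9b (2.93) in Vax B and Csf1 (3.88), Sdcbp2 (3.46) and Nrp1 (3.18) in Vax C, where Csf1 encodes a growth factor of macrophages. Activation receptor genes were higher in 8 and 10 of 13, with Icos (2.17), Itga1 (2.10) and Cxcr6 (2.09) in Vax B. Genes listed as regulatory T cell effectors were higher in 8 and 9 of 13, led by the growth factor gene Areg at 3.02 and 3.76 and by Nrp1 at 2.49 and 3.18, while Foxp3 itself stood at -0.04 and -0.71. Cell cycle genes were lower in 20 of 21 in both arms (medians -1.84 and -1.77), such as Cdc20 at -2.43 and -2.38.

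Interferon-stimulated genes of CD8 T-like cells had medians of 0.01 in Vax A, -0.51 in Vax B and -0.81 in Vax C, with 10 and 18 of 27 at least 1.5-fold lower in the last pair of arms, such as Oasl2 at -1.97 and -1.78 and Isg15 at -1.26 (95% interval -1.29 to -1.23) in Vax C. The Vax A median turned to -0.02 as the mean of each cell's CPM and to -0.03 after thinning. Cgas stood at -0.23, -1.57 and -1.43, Irf7 at -0.03, -0.88 and -0.92, Tmem173 at 0.21, -0.03 and -0.09, Tbk1 at 0.16, 0.68 and 0.41 and Irf3 at -0.09, -0.05 and 0.08. No Ifnb1 UMI was seen in CD8 T-like cells of any arm, which allows up to 0.147 CPM in Ctrl. Dissociation and heat-shock genes were higher, in 7, 9 and 13 of 17, with Egr1 at 1.27 in Vax B and 2.16 in Vax C, and inflammatory genes gave medians of 0.71, 0.56 and 1.17. Interferon-gamma response genes gave 0.44, 0.21 and -0.04, the Vax B value turning to -0.05 as the mean of each cell's CPM and to -0.04 after thinning. Genes of sensing gave 0.25, 0.20 and 0.02 (the last -0.05 with TMM scaling), MHC class I genes 0.22, 0.24 and 0.21, hypoxia genes 0.11, -0.10 and -0.27 (the last 2 at 0.15 and 0.05 as the mean of each cell's CPM) and ribosomal protein genes -0.03, -0.28 and -0.24. Cd274 was at 0.49, 0.56 and 0.33, the last -0.08 at a Leiden resolution of 2.0. Cxcl9, Apoe, Spp1 and MHC class II transcripts in these cells are abundant in mononuclear phagocyte-like cells of the same tumours, so free RNA is left open for them and their ratios are not described. The median of all genes in Vax C was 0.12, and 0.04 with TMM scaling.

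Set against Vax A, CD8 T-like cells of Vax B had higher exhaustion genes in 13 of 17 (median 1.22 (member bootstrap 0.60 to 1.47)) and lower stem-like genes in 12 of 16 (median -1.23), with Pdcd1 at 1.55 (95% interval 1.52 to 1.58) and Tcf7 at -2.74 (95% interval -2.82 to -2.67). Ifng was lower at -1.22 (95% interval -1.24 to -1.2), Gzmb at -0.70, and the granzyme genes Gzmg (3.88), Gzmd (2.51) and Gzmf (2.47) were higher. In Vax C over Vax A, exhaustion genes were higher in 13 of 17 (median 1.39 (member bootstrap 0.76 to 1.59)), including Nr4a2 (1.94), Rgs16 (1.94) and Tigit (1.87) and Tox at 1.59. Stem-like genes were lower in 9 of 16, interferon-stimulated genes in 19 of 27 and Gzmb stood at -0.98, while Gzmd (3.63) and Gzme (3.28) were higher. A cluster of CD8 T-like cells marked by Tcf7 held 52.7% of them in Ctrl, 50.03% in Vax A, 4.90% in Vax B and 7.79% in Vax C.

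**Figure D3:**
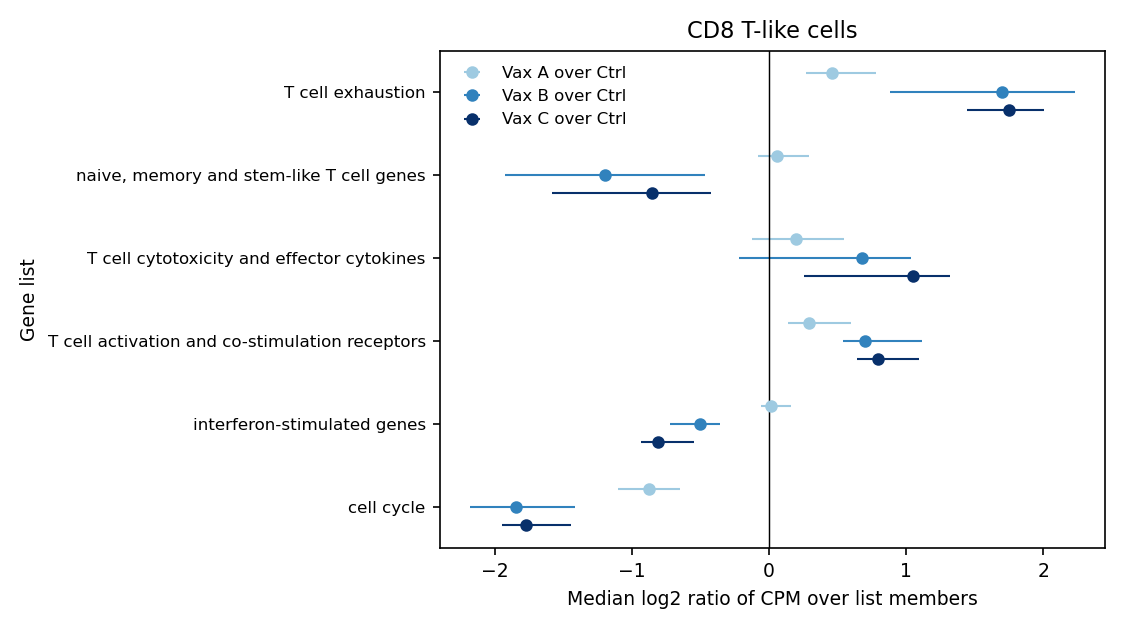
Median log2 ratio of CPM to Ctrl (horizontal axis) over the measured members of each gene list in CD8 T-like cells, for Vax A, Vax B and Vax C, with lines for the 95% bootstrap over list members. T cell exhaustion genes lie at 0.46, 1.70 and 1.75, and naive, memory and stem-like genes at 0.06, -1.19 and -0.85.

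E7-specific cells were counted with the dextramer. At least 10 dextramer UMIs were carried by 1.28% (0.836% to 1.87%) of CD8 T-like cells in Ctrl, 15.4% (14.3% to 16.6%) in Vax A, 57.8% (56.7% to 58.9%) in Vax B and 52.4% (51.2% to 53.6%) in Vax C. Mononuclear phagocyte-like cells, which lack a T cell receptor and come from the separate CD45+CD3- libraries, gave 0.889%, 0.216%, 0.0284% and 0.202% at median depths of 3409, 4515.5, 3899.5 and 4544 antibody UMIs, against 2550, 3292.5, 3204 and 3426 in the CD8 T-like cells. Within the CD3+ libraries, regulatory T-like cells gave 0.980%, 1.24%, 5.33% and 3.06% at median depths of 2009, 3023, 2376 and 2656, CD4 conventional T-like cells 0.931%, 3.14%, 11.7% and 4.49%, and unnamed T cells 0.730%, 0.364%, 2.42% and 2.27%, so the Ctrl share is close to that of other classes. The minimum was chosen after the counts were seen, and at 20 UMIs the shares were 0.737%, 12.4%, 43.3% and 31.6%. In CD8 T-like cells with the dextramer, compared with those of the same library without a dextramer UMI, exhaustion genes had medians of 1.63 in Vax A, 0.98 in Vax B and 1.86 in Vax C and stem-like genes -1.77, -1.04 and -1.48. Lists of myeloid genes were higher in some arms, MHC class II genes at 0.63 in Vax B and 1.1 in Vax C, immunosuppressive myeloid genes at 0.56, 0.0228 and 0.75 and lipid-handling genes at 0.70, 0.13 and 0.76 in Vax A, Vax B and Vax C. Free RNA or attached myeloid material is left open for these. The immunosuppressive myeloid list also holds Havcr2 and Entpd1 of the exhaustion list, so its medians are not separate from that list. Among single genes, Havcr2 was at 2.71, 1.23 and 2.60, Lag3 at 2.68, 1.49 and 2.41, and Tcf7 at -3.16, -3.08 and -4.02. Interferon-stimulated genes were lower in the dextramer-binding cells, with medians of -0.85, -0.63 and -0.90. In cells without a dextramer UMI, exhaustion genes over Ctrl gave -0.15 in Vax A, 1.2 (member bootstrap 0.11 to 1.23) in Vax B and 0.48 (0.01 to 0.55) in Vax C.

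Antibody counts for inhibitory receptors on CD8 T-like cells were higher in Vax B and Vax C than in Ctrl or Vax A. The median PD-1 (CD279) count per cell was 6 UMIs in Ctrl, 7 in Vax A, 82 in Vax B and 104 in Vax C. TIM-3 (CD366) had medians of 8, 6, 74 and 91 UMIs, and LAG-3 (CD223) 12, 10, 59 and 67. Antibodies against antigens of myeloid cells also differed on these cells, with medians of 33, 48, 84 and 137 for MHC class II (IAIE) and 12, 13, 23 and 32 for CD11c. F4/80 (F480), at 13, 7, 10 and 21, and CD11b, at 40, 31, 38 and 49, were above Ctrl in Vax C only. As a share of all antibody UMIs of the class, CD279 was 0.811%, 0.877%, 2.55% and 3.07%, log2 ratios to Ctrl of 0.11, 1.65 and 1.92, and CD366 0.836%, 0.768%, 2.80% and 3.53%, ratios of -0.12, 1.75 and 2.08. As a centred log ratio per cell, the CD279 differences were larger, at 0.42, 2.95 and 2.94. TIGIT counts stayed low, with medians of 6, 4, 8 and 12 UMIs, and its share of antibody UMIs was 0.649%, 0.245%, 0.3305% and 0.468%, below Ctrl in each vaccinated arm, unlike its transcript. On mononuclear phagocyte-like cells, which come from other libraries, its share was 0.609%, 0.262%, 0.159% and 0.201%. The lower share is thus not particular to CD8 T-like cells and is not read as less TIGIT protein. CD44, a marker of antigen-experienced cells, had medians of 384, 532, 781 and 812 UMIs, and Ly6C 1253.5, 1530.5, 831 and 405. On mononuclear phagocyte-like cells, Ly6C, high on monocytes, had medians of 346, 1448.5, 1400 and 710 UMIs, the macrophage antigen F4/80 (F480) 69, 32, 23 and 62, and MHC class II (IAIE) 245, 298, 139 and 732. IAIE medians were 53, 118, 92 and 269 in monocyte-like and 343, 1232, 1062 and 2237.5 in macrophage-like cells, above Ctrl in each vaccinated arm. F480 medians were 32, 25, 20 and 34 in monocyte-like and 93, 113, 92.5 and 202.5 in macrophage-like cells. The class medians thus also follow the shares of its parts. An antibody share is relative to the other antibodies of the panel.

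Receptor sequences showed more cells in expanded clones in Vax B and Vax C than in Ctrl, in CD8 T-like but not in regulatory T-like cells. Of 8885, 8460 and 7815 cells with a receptor in Ctrl, Vax B and Vax C, 11.4% (10.8% to 12.1%), 61.7% (60.7% to 62.8%) and 64.1% (63.0% to 65.1%) belonged to clones of at least 10 cells, log2 ratios to Ctrl of 2.43 in Vax B and 2.49 in Vax C. The largest 10 clones held 3.44%, 22.9% and 39.1% of the cells, and the Gini coefficient of clone size was 0.259, 0.680 and 0.699. Clones of at least 2 cells held 36.7%, 77.4% and 76.5%. With 7815 cells drawn from each library, 9.74%, 60.9% and 64.1% were in clones of at least 10 cells. Among CD8 T-like cells the shares in such clones were 13.2%, 72.9% and 77.4%, and with 1878 CD8 T-like cells drawn from each library and clones counted among them 10.5%, 53.3% and 64.5%. Regulatory T-like cells went the other way, at 14.4% of 3356 cells, 0.185% of 541 and 0 of 381 (up to 0.787%). CD4 conventional T-like cells gave 13.4%, 11.7% and 2.04%. CD8 T-like cells with the dextramer were in such clones in 34.6% of 26 cells in Ctrl, 78.8% in Vax B and 88.6% in Vax C, and those without a dextramer UMI in 12.0%, 58.2% and 29.7%. The largest clone of Vax C had 835 cells with TRBV10 and TRAV4-3, of which 63.9% carried the dextramer, and that of Vax B 350 cells with TRBV15 and TRAV16N, of which 42.1% did. In Vax B the sixth largest clone, with 152 cells, TRBV12-2 and TRAV7D-5, was at 1.32%. Few clones were shared, 5 between Ctrl and Vax B, 1 between Ctrl and Vax C and 11 between Vax B and Vax C. The receptors of Vax A were not analysed here, because no file of them was available.

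**Figure D4:**
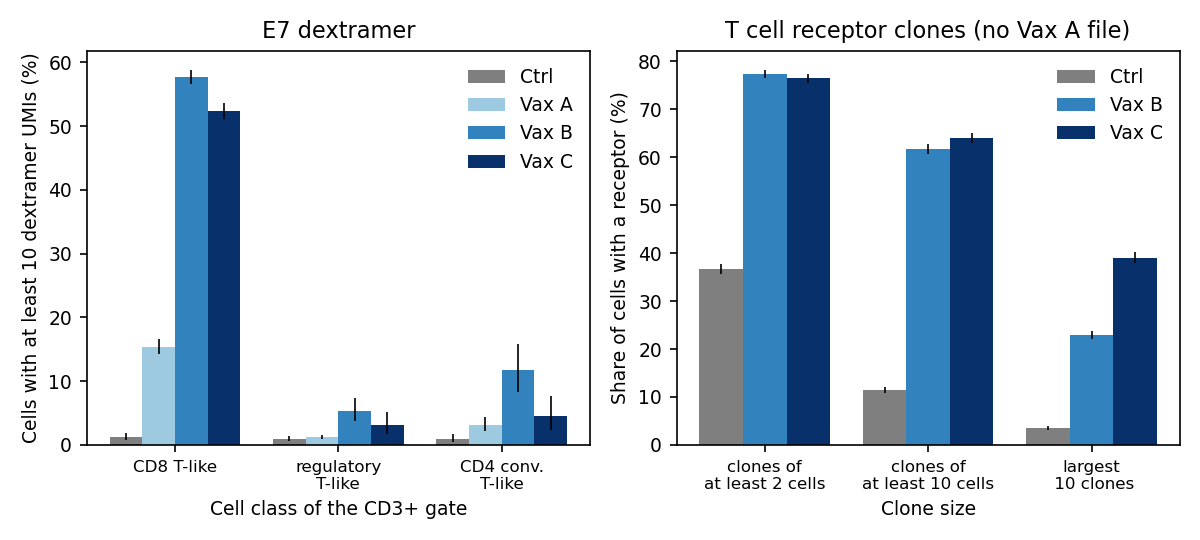
Left, share (%) of cells of 3 CD3+ classes with at least 10 dextramer UMIs in each arm, and right, share (%) of cells with a receptor in clones of at least 2 cells, of at least 10 cells and in the largest 10 clones, for Ctrl, Vax B and Vax C, bars being 1 library each with exact 95% binomial intervals. The dextramer share of CD8 T-like cells goes from 1.28% in Ctrl to 57.8% in Vax B, and the share in clones of at least 10 cells from 11.4% to 61.7%.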

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

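Among the tests named here, the one for droplets with 2 cells was chosen only after the result was seen.

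CD8 T-like cells were found in the CD45+CD3- gate, which was sorted for cells without surface CD3. Their share exceeded that of Ctrl (0.0427%, 0.0139% to 0.0997%, 5 cells) in Vax B at 0.286% (0.188% to 0.415%, 27 cells) and in Vax C at 3.02% (2.68% to 3.40%, 271 cells). In Vax A it was 0.148% (0.0828% to 0.244%, 15 cells), with an interval that overlaps that of Ctrl. In Vax C these cells held fewer UMIs than CD8 T-like cells of the CD3+ gate (a ratio of medians of 0.723, 4384 against 6066). This cannot decide on droplets with a T cell and a myeloid cell, because clusters with both kinds of genes had already been set apart as mixed. In this gate of Vax C those held 185 barcodes at a median of 17601 UMIs. In the CD8 T-like cells that were left, C1qa (218 against 34.4 CPM) and Lyz2 (343 against 33.9 CPM) were higher, and free RNA was not tested as their source. Only 0.738% of the barcodes were also in the CD3+ matrix, against 1.36% of mononuclear phagocyte-like barcodes, which argues against carry-over between libraries. For T cells that passed the sort regardless of their state, a dextramer share like that of the CD3+ gate was predicted. It was 10.7% (7.28% to 15%) against 52.4%, a difference of -41.7 percentage points. Median antibody depths were 2085 and 3426 UMIs, with 1.65 against 4.74 dextramer UMIs per 1000 antibody UMIs. The difference cannot decide on this, because the dextramer binds the receptor and a sort without surface CD3 may favour cells with little of it. Among the genes always named, Pdcd1 was at 1261 against 1007 CPM, Ifng at 901 against 1032, Gzmb at 2121 against 2789 and Tcf7 at 13.8 against 49.1. A hypothesis left open is that these cells may have carried little receptor on their surface, since Cd3e was at 2152 CPM against 2073 (this gene, C1qa and Lyz2 were chosen after their values were seen), and the panel has no antibody against CD3 or the receptor to test it.

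Interferon-stimulated genes of mononuclear phagocyte-like cells were higher than in Ctrl in Vax A (median log2 ratio 0.63) and slightly lower in Vax C (-0.17, or -0.0432 with TMM scaling), a difference of -0.80 that was not tested. The medians were -0.63 and -0.96 in monocyte-like and 0.28 and -0.47 in macrophage-like cells, so in Vax A the value of the class lies above those of both parts and has the opposite sign in the larger one. Lipid-handling and lysosomal genes of the same cells were lower in Vax A (-0.75) and in Vax B (-0.46) and slightly higher in Vax C (0.07), differences of 0.82 and 0.53 that were not tested either. Medians of the parts are not given here for this list, so levels within the parts are not separated from their shares.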

How the results depend on the processing

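Of the alternatives below, those that leave out the highest doublet scores, count T-like cells only, leave out the intermediate clusters, use barcodes with 1 TRA and 1 TRB chain or CD8 T-like cells only, or use 5 or 20 dextramer UMIs were added after the data were seen. No paired analysis was possible because the labels give 1 library per arm and gate and no key that joins animals. The alternative of keeping doublets, chosen before the data were examined, equals the reported values, since none were removed, for cells and surface proteins alike. Of 202 values of the leading results under alternatives, 143 stayed inside the interval of the reported value, 58 lay outside it with the same sign and 1 reversed. Of 1442 values of named genes, 920 stayed inside the interval (915 with the same sign), 511 lay outside it (508 with the same sign) and 11, of 7 genes, reversed, which here means a change of sign where the interval of the reported value leaves out 0. For the other 5 and 3 values with a changed sign that interval held 0. Over all settings the interferon-gamma response of mononuclear phagocyte-like cells lay between 2.08 and 2.33 in Vax A, 1.72 and 2.13 in Vax B and 1.33 and 1.62 in Vax C, the stem-like list of CD8 T-like cells between -1.57 and -0.89 in Vax B, and the NK-like share between 2.38 and 2.47 in Vax A and -0.77 and -0.65 in Vax C. Replicate mice are lacking under every setting. The cause was not tested for any value that follows, except that other class boundaries and denominators change shares by construction.

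The macrophage-like share (log2 ratio to Ctrl in Vax A, Vax B and Vax C) was -2.26, -3.41 and -1.05 at a Leiden resolution of 0.5 and -2.28, -2.96 and -0.74 at 2.0. The monocyte-like share was 1.75, 1.95 and 1.48 at 0.5 and 1.42, 1.72 and 0.86 at 2.0, and 2.20 and 2.60 in Vax A and Vax B without the highest doublet scores. Among T-like cells only, the CD8 T-like share was 0.40, 1.81 and 1.79, and without the highest doublet scores 2.04 in Vax B. The regulatory T-like share of Vax A was 0.0209 without the highest doublet scores and reversed to -0.24 among T-like cells only. That of Vax B was -2.21 at a resolution of 0.5, -2.20 at 2.0 and -2.74 among T-like cells only, and that of Vax C -2.72 at 2.0. With TMM scaling, interferon-stimulated genes of mononuclear phagocyte-like cells were at 0.40 in Vax B. The exhaustion list of CD8 T-like cells of Vax C was 2.12 as the mean of each cell's CPM and 2.08 with cells thinned.

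Antibody ratios in CD8 T-like cells (Vax A, Vax B and Vax C) as a centred log ratio were 0.42, 2.95 and 2.94 for CD279 and -0.16, 2.46 and 2.37 for CD366. Without the highest doublet scores they were 0.0884, 1.69 and 1.96 for CD279 and -0.15, 1.76 and 2.11 for CD366. The share in clones of at least 10 cells (log2 ratio in Vax B and Vax C) was 2.18 and 2.21 by TRB CDR3 and V gene alone, 2.64 and 2.70 for T-like barcodes, 2.64 and 2.72 at equal numbers of cells, 2.19 and 2.23 with 1 TRA and 1 TRB chain, 2.57 and 2.62 without the highest doublet scores and 2.78 and 2.87 for CD8 T-like cells. The dextramer share of CD8 T-like cells in Ctrl, Vax A, Vax B and Vax C was 3.05%, 18.2%, 68.3% and 67.9% at 5 UMIs and 0.737%, 12.4%, 43.3% and 31.6% at 20.

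Genes that reversed in mononuclear phagocyte-like cells were H2-Ab1 in Vax A at -0.0146 (resolution 0.5) and -0.24 (without the intermediate clusters), Irf7 in Vax B at 0.0110, Irf3 in Vax C at 0.0483 and Cxcl10 in Vax C at 0.0888 (all TMM scaling), and Cxcl10 at 0.0320 without the intermediate clusters. In CD8 T-like cells they were Tcf7 in Vax A at -0.0203 (mean of each cell's CPM) and -0.0302 (thinned), Gzmb in Vax B at 0.16 and 0.14 under the same settings, and Cd274 in Vax C at -0.0794 (resolution 2.0). Of list medians of at least 0.25 in size, 5 of 484 values in CD8 T-like cells and 2 of 513 in mononuclear phagocyte-like cells had the opposite sign under an alternative.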

Other observations

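Conventional DC-like cells of Vax A and Vax B had higher interferon genes of both kinds than those of Ctrl. Interferon-gamma response genes were at least 1.5-fold higher in 17 of 18 in Vax A (median log2 ratio 2.11 (member bootstrap 1.69 to 2.56)) and in 17 of 18 in Vax B (1.98), with Iigp1 at 3.79 (95% interval 3.42 to 4.18) in Vax A and Gbp2 at 3.62 (95% interval 3.47 to 3.78) in Vax B. Interferon-stimulated genes were higher in 24 and 21 of 29 (medians 0.85 and 0.74), such as Ifi47 at 1.88 and 1.81. Cd40, through which T cells license these cells, was at 1.51 and 1.32, while MHC class II genes were level (medians -0.07 and -0.27). Ly6C antibody, high on monocytes, had medians of 100, 273.5 and 192 UMIs on this class in Ctrl, Vax A and Vax B. Its share of antibody UMIs was 8.79%, 12.5% and 16.0%, while that of CD11b was 14.0%, 12.8% and 13.8%. Monocyte-like cells placed in this class were not tested as a source of these genes. NK-like cells had higher cytotoxicity genes in Vax A, 13 of 22 at a median of 0.77 with Ccl5 at 1.33, and fewer in Vax B, 7 of 22 at 0.27. Their cell cycle genes were lower, 13 and 15 of 20, with Ccnb2 at -2.46 and -2.19.

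Regulatory T-like cells carried more effector cytokine and killing genes in each vaccinated arm than in Ctrl. Cytotoxicity genes were higher in 15 of 18 in Vax A, 11 of 17 in Vax B and 10 of 18 in Vax C (medians 1.07, 1.19 and 0.87), with Ifng at 2.97 (95% interval 2.80 to 3.14), 1.93 and 1.65. The class also carried CD8a antibody, with medians of 7, 7, 18 and 17 UMIs in Ctrl, Vax A, Vax B and Vax C. Its share of antibody UMIs was 1.16% in Ctrl and 1.40% in Vax A, and 0.880% and 0.477% without the highest doublet scores. These genes are thus not read as a trait of regulatory T cells alone. The list of regulatory T cell effector genes was near Ctrl, at 0.11, 0.24 and 0.17, although Il10, an inhibitory cytokine gene, stood at 0.84, 1.34 and 0.72. Interferon-gamma response genes had medians of 0.69, 0.52 and 0.35, and cell cycle genes -0.59, -0.93 and 0.24. Median antibody counts on these cells were 83, 185, 117 and 93 UMIs for 4-1BB (CD137) and 202, 370, 304 and 302 for OX40 (CD134) in Ctrl, Vax A, Vax B and Vax C. Their median depths were 2009, 3023, 2376 and 2656 antibody UMIs. As a share of antibody UMIs, CD137 was 4.99%, 6.85%, 5.92% and 4.61%, below Ctrl in Vax C, and CD134 12.2%, 14.8%, 14.6% and 13.0%. CD4 conventional T-like cells had higher Gzmk at 1.52, 2.64 and 2.15 and Prf1 at 1.39, 2.39 and 2.40, and lower hypoxia and glycolysis genes in Vax B (11 of 16, median -0.78) and Vax C (6 of 16, -0.49). In Vax B, 11.7% of the CD4 conventional T-like cells carried the class I dextramer, and of the 27 of these with a receptor 70.4% were in clones of at least 10 cells, against 3.57% of the 168 without a dextramer UMI, so CD8 T cells placed in this class are left open as a source of its Gzmk and Prf1. None of these differences was tested, and the classes hold 251 conventional DC-like cells and 266 NK-like cells at the fewest. Neither free RNA of CD8 T-like cells nor droplets that also held such a cell were tested for the granzyme and Ifng transcripts.

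In the tests that follow, those on receptors in mixed barcodes, on loading, on thinned cells and on cells without a dextramer UMI were chosen only after the results were seen.

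Barcodes with both T cell and myeloid genes in the CD3+ gate numbered 2146 in Ctrl, 52 in Vax A, 277 in Vax B and 1210 in Vax C. The tables argue against single myeloid cells as all of them, since 51.5% (49.4% to 53.7%) of those of Ctrl had a T cell receptor, against 88.0% of T-like barcodes, and against more loading of Ctrl than of Vax A, as the Ctrl matrix had 0.912 times as many barcodes. Droplets with a T cell and a myeloid cell cannot be told apart from other sources: T cell gene UMIs per mixed barcode were 0.539 of those per T-like barcode in Ctrl, but 0.884 in Vax B and 0.984 in Vax C, and median UMIs in Ctrl were 14541.5 against 5412. A sort or dissociation that left more cells attached in Ctrl and Vax C could give the same counts, and no library was repeated to tell.

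The higher exhaustion list in CD8 T-like cells of Vax B and Vax C was weighed against 3 other readings. Dissociation stress was not among them and was not tested, although dissociation and heat-shock genes were also higher in these cells of both arms. Without the members that are higher in mononuclear phagocyte-like cells, the lower of the medians of the arms was 1.74, which argues against free RNA of myeloid cells, and greater depth is argued against because CD8 T-like cells of Vax B and Vax C were shallower than those of Ctrl (medians of 7132 and 6066 against 7710.5 UMIs), the median being 2.01 with every cell thinned to 2000 UMIs. Cells without a dextramer UMI had a median over those of Ctrl of 1.2 (member bootstrap 0.11 to 1.23) in Vax B, so the cells counted as dextramer-binding are not its only source there, while in Vax C the median of 0.48 (0.01 to 0.55) is between what either case would give, and the cases cannot be told apart. E7-specific cells as the only source are left open in both arms, because a cell without a dextramer UMI may still be specific for E7, 58.2% of such cells in Vax B were in clones of at least 10 cells, and few list members, 15 and 14, were measured. No biological explanation was tested, and vaccination stays open as one, since each arm is 1 library.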
